A study of Mus musculus with 18 samples.

How the data were processed

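Single-cell RNA sequencing had been done on ovaries of 17 mice in 4 groups, with both ovaries of an animal (2 per animal) in 1 library, and on 1 further library of ovarian cells sorted for a high signal of SPiDER-βGal, a fluorescent substrate of the lysosomal enzyme beta-galactosidase. Per the labels, the groups were young mice with regular cycles at 4.5 months (n = 5), mice with regular cycles at 10.5 months (n = 3), mice with irregular cycles at 10.5 months (n = 4) and mice without cycles after estropause at 15.5 months (n = 5). They are called young regular, peri-estropausal regular, peri-estropausal irregular and post-estropausal acyclic here. The unsorted ovaries were taken at diestrus, and ovaries were collected on different days, but no day is given for a library. The sorted cells came from post-estropausal ovaries, and how many animals they came from is not stated.

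The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger against the mouse genome mm10 and already limited to barcodes called as cells. Per the file headers, version 7.2.0 made the 17 unsorted matrices, with 32285 genes, and version 8.0.1 made the sorted matrix, with 33696 genes, although the labels give 7.2.0 for the sorted library. The 31950 gene identifiers held by both were used wherever the libraries were set side by side. Total counts per unsorted library ranged from 50174763 to 177091816 UMIs over 2962 to 7353 barcodes, and the sorted library held 28025913 UMIs over 6200 barcodes.

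Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept. Doublet scores came from Scrublet through scanpy 1.11.5, and the highest-scoring barcodes of each library were removed at a rate of 0.8% per 1000 barcodes, which gave 2.37% to 5.88% and 3014 barcodes in the unsorted libraries. Kept cells numbered 65886 unsorted (1807 to 6520 per library) and 4751 sorted. Counts were scaled per cell and log-transformed, 2000 variable genes gave 40 principal components, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, resolution 1) on shared neighbours among 20 neighbours gave 38 clusters. A cluster was named by marker lists for 23 cell types, each scored as the mean height of its markers above their median over clusters, relative to the highest cluster. The lists were set before the data were examined, but the scoring and the thresholds that accept a name were not in the design and were set after the data were seen: a score of at least 0.15, 3 markers found in at least 5% of cells, and, where the next score came near the best or the cells had few UMIs, markers among the 10 leading genes of the cluster. A cluster whose leading genes held more markers of another type was left unnamed or took that type. These left 6 clusters unnamed and gave 16 classes from 32 clusters. Class names such as granulosa therefore mean granulosa-like by markers. Each sorted cell took the class of most of its 15 nearest unsorted cells in the same component space. That a class holds its own markers is not a result; where such a gene differed between groups of libraries, it is called a marker.

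The library, not the cell, was the replicate throughout. The design, the comparisons, the gene lists, the rule for the genes named and most of the alternatives were fixed before the data were examined. Class shares of all kept cells were compared by exact two-sided permutation tests on the difference of means (scipy 1.17.1), with Benjamini-Hochberg adjustment over the classes that held at least 0.1% of cells, per comparison; the immune total was tested on its own. For expression, counts were summed per library and class where the library had at least 20 cells of the class, and a comparison needed at least 3 such libraries in each group. The sums were tested with edgeR 4.0.16 (quasi-likelihood, TMM normalisation, filterByExpr) in R 4.3.3, in 1 fit of all 4 groups per class, and genes with adjusted p under 0.05 within a class and comparison were called. The 7 classes tested for post-estropausal acyclic against young regular were granulosa, luteal, theca (steroidogenic), stromal, endothelial, macrophage and T cells; the 3 stepwise comparisons were limited to granulosa, stromal and macrophage cells. CPM values of tested classes are TMM-normalised, those of whole libraries and of the comparison with the sorted library use plain totals, and errors of log2 fold changes are standard errors; other errors are SD.

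The 17 gene lists were senescence regulators, secreted senescence-associated factors, lysosome, steroid hormone synthesis, cholesterol synthesis, collagen and extracellular matrix, interferon response, antigen presentation, inflammatory NF-kB response, dissociation stress, oxidative phosphorylation, ribosomal proteins, proliferation, p53 targets and DNA damage, granulosa hormone and follicle genes, lipid-laden macrophage genes, and T cell effector and exhaustion genes. Lists overlap each other and some hold class markers. A list with at least 5 members in a class was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over all 262 tests together, with camera at an estimated correlation and fry beside it. Member calls are given over all genes tested and adjusted over the list alone.

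Genes were named by a fixed rule: up to 6 that rose and 6 that fell most in each class (4 and 4 in a stepwise comparison) among called genes with average log2 CPM of at least 5, group values that did not overlap, and a mean CPM of at least 1 in 5 of that in the class where the gene was highest; up to 4 leading members of each list that passed; and Cdkn2a, Cdkn2b and Cdkn1a in every class. Predicted genes, mitochondrial, ribosomal and hemoglobin genes were left out of that choice. Gene positions are from the mm10 annotation. Cdkn2a and Cdkn1a were also compared in whole libraries on log2(CPM + 1).

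The single sorted library was described without a test. Its class shares have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only, and a count of 0 was read as up to 3 counts. In classes with at least 50 sorted cells, log2(CPM + 1) of summed counts was set against the mean of the post-estropausal acyclic libraries. The design asked for all 5 of these; those with fewer than 20 cells of a class were left out, and at least 3 were required, so that 8 classes were compared. Each list's median was ranked against 10000 random lists of the same size matched on expression in 20 bins, with members limited to a mean CPM of at least 1, a limit set after the data were seen.

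The test was checked on simulated counts with 200 genes changed, so its rates may not hold for real data. For acyclic against young, 95% of 2-fold and 99% of 4-fold changes were recovered in granulosa cells, and 57% and 92% in luteal cells. False calls were 4.43% and 2.61% of calls. Among the 29 pairs of libraries within a group (pairs across groups were not compared), chi-square per degree of freedom was 41.6 to 553, so no pair looked like a copy. The labels name no batch, litter or day behind a replicate number. Same-number libraries of post-estropausal acyclic and young regular mice were no more alike than others (correlations of deviations from group means -0.162 to 0.165 in whole libraries). Between irregular and regular mice all 3 same-number pairs correlated in granulosa cells (0.193 to 0.667, other pairs at most 0.0749) and less so in whole libraries (0.0396 to 0.414, others at most 0.187). The planned fit has no block; a replicate block was run as an alternative, and the blocked values are given beside the comparison of irregular with regular mice. Alternatives also changed the test (DESeq2 1.42.0), the normalisation, the filters, doublet removal, the clustering resolution (2, with 51 clusters), the cell minimum (50), the denominators and pseudocounts, and left out each library in turn. Alternatives chosen after seeing the data were the looser barcode limits (200 genes, no mitochondrial limit), counting cluster 15 as granulosa, a denominator of named classes only, the clusters held by both groups only, and leaving out post-estropausal acyclic replicates 2 and 3. Other splits of the libraries were limited to 60 for the largest granulosa comparisons, and to 100 elsewhere.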

Results

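Single-cell RNA sequencing measured gene expression, as UMI counts, in the ovaries of 17 mice, 1 library per animal, and in 1 library of sorted ovarian cells. The groups were 5 young regular mice at 4.5 months, 3 peri-estropausal regular and 4 peri-estropausal irregular mice at 10.5 months, and 5 post-estropausal acyclic mice at 15.5 months. Unsorted libraries had medians of 13703 to 25443 UMIs per kept cell, and the sorted library 4465. Of the cell barcodes, 88.5% ± 7.05 (SD, n = 5) were kept in young regular libraries and 59.7% ± 6.62 (SD, n = 5) in post-estropausal acyclic libraries. Barcodes with few genes or UMIs made up 8.70% ± 5.87 and 35.9% ± 5.35 of these. Loss of cycles and age change together between these groups, so the comparison of acyclic with young mice covers both.

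The first question was which ovarian cell types differ in share between young regular and post-estropausal acyclic mice. Stromal cells, the collagen-making fibroblast-like cells of the ovary, made up 12.3% ± 4.33 of kept cells in young regular libraries and 2.01% ± 1.50 in post-estropausal acyclic libraries (SD, n = 5 each). Smooth muscle or pericyte cells, which wrap vessels and follicles, made up 3.84% ± 1.90 and 0.869% ± 0.71. Endothelial cells, the lining of blood vessels, made up 4.38% ± 0.754 and 1.64% ± 1.39. In all 3 classes, 5 of 5 acyclic libraries lay below every young library. Surface epithelial cells were higher in acyclic libraries, at 6.40% ± 3.97 against 2.09% ± 0.566, and neutrophils were at 0.491% ± 0.463 against 0.0706% ± 0.0308, with 5 of 5 acyclic libraries above every young one. Each of these 5 classes had p = 0.00794 in the exact two-sided permutation test, the smallest this design gives, and an adjusted p of 0.0254 over 16 classes. T cells were at 1.88% ± 1.54 against 0.599% ± 0.251, with 4 of 5 acyclic libraries above every young one (exact permutation p = 0.0159, adjusted 0.0423). All immune classes together held 7.13% ± 2.73 and 3.78% ± 0.779 (exact permutation p = 0.0159).

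The other 10 classes did not pass. Granulosa cells, which surround the oocyte and make estradiol, were at 39.1% ± 13.4 in acyclic and 48.4% ± 8.30 in young libraries (adjusted p = 0.300 in the exact test). Theca cells, which make androgens, were at 6.79% ± 4.45 and 13.3% ± 4.05, and B cells at 1.4% ± 0.916 and 0.403% ± 0.103 (adjusted p = 0.0847 each, exact test). Mast cells were at 0.127% ± 0.0782 and 0.0263% ± 0.0249 (adjusted p = 0.0544, exact test). Luteal cells, of the progesterone-making corpus luteum, were at 6.88% ± 7.69 and 4.77% ± 0.751, and macrophages at 1.99% ± 0.602 and 1.66% ± 0.331. Clusters without a name held 28.7% ± 22.9 of kept cells in acyclic libraries and 2.31% ± 1.54 in young ones. One of them, cluster 15, held 49.9% and 22.7% of acyclic replicates 2 and 3, at most 1.13% of the other acyclic libraries, 3.83% of irregular replicate 3 and 0% of young cells, with close scores for granulosa and theca markers. The luteal mean of acyclic libraries rests on replicate 4 (18.8%, others at most 9.79%), without which the difference was -0.876 in place of 2.12; on the log2 scale it was -0.641. The number of classes that passed fell from 6 to 3 over cells other than granulosa and luteal, to 3 with looser barcode limits (epithelial cells, neutrophils and T cells lost, and the immune difference at 1.34 in place of 3.35, exact p = 0.175), to 3 without post-estropausal acyclic replicate 2 (T, endothelial and smooth muscle or pericyte cells lost), and to 0 without any 1 of young regular replicates 1, 2, 3, 4 or 5. Without acyclic replicate 5 the differences of T cells and the immune total were 0.598 and 2.23 in place of 1.28 and 3.35, T cells no longer passed, and without acyclic replicate 1 that of neutrophils was 0.226 in place of 0.420.

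**Figure D1:**
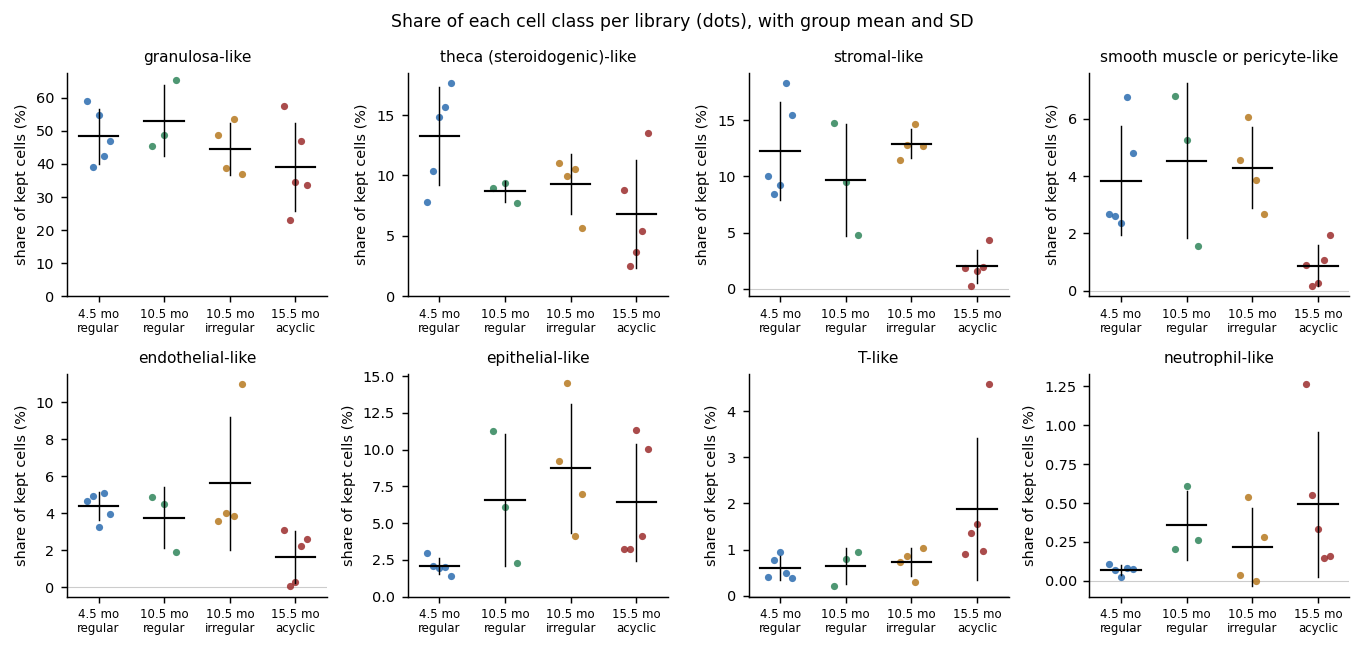
Share of kept cells (%) of 8 cell classes in each unsorted library (dots), with the mean and SD of each of the 4 groups. Stromal cells averaged 12.3% in young regular and 2.01% in post-estropausal acyclic libraries.

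The stepwise comparisons asked whether shares differ with age while cycles stay regular, with cycle regularity at 10.5 months, and with the loss of cycles. From irregular to acyclic, stromal cells were lower, at 12.9% ± 1.3 (SD, n = 4) against 2.01% ± 1.50 (n = 5). Smooth muscle or pericyte cells were at 4.29% ± 1.41 against 0.869% ± 0.71 and endothelial cells at 5.60% ± 3.60 against 1.64% ± 1.39. In each, 5 of 5 acyclic libraries lay below every irregular one (exact two-sided permutation p = 0.00794, adjusted 0.0423). T cells were at 0.729% ± 0.311 and 1.88% ± 1.54 (adjusted p = 0.381, exact test). The 3 calls fell to 0 over cells other than granulosa and luteal, and on the log2 scale, and without irregular replicate 4 the endothelial difference was -2.16 in place of -3.96. Between young regular and peri-estropausal regular mice (n = 3) no class passed the exact test. Epithelial cells were at 6.56% ± 4.48 in the latter (exact p = 0.0357) and neutrophils at 0.357% ± 0.221 (exact p = 0.0179, the smallest possible), with an adjusted p of 0.286 each. Between regular and irregular mice no class passed, and the smallest p was 0.0286, the smallest possible, for oocyte-like cells (exact test, adjusted 0.457). With 16 classes and so few libraries no single class could pass in either of these comparisons by itself.

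Granulosa cells were compared between post-estropausal acyclic and young regular mice. Expression fell for Shroom3, a regulator of actin and cell shape, from 266 ± 65.9 to 14.4 ± 9.81 CPM (SD, n = 5 each; log2 change -4.18 ± 0.46, SE; adjusted p = 1.3e-05). It also fell for Ghr, the growth hormone receptor, from 242 ± 44.8 to 23.5 ± 27.8 CPM (log2 -3.34 ± 0.58) and for Ccn2, a secreted matrix protein, from 101 ± 21.2 to 9.14 ± 14.0 CPM (log2 -3.39 ± 0.69). Grem1, a secreted BMP antagonist, rose from 29.9 ± 6.45 to 285 ± 212 CPM (adjusted p = 9.9e-05), and Nppc, the C-type natriuretic peptide that holds the oocyte in meiotic arrest, from 98.8 ± 17.2 to 515 ± 237 CPM (log2 2.38 ± 0.31). Hsd3b1, a steroid-making enzyme, rose from 565 ± 69.3 to 1945 ± 652 CPM. The markers Hsd17b1, which makes estradiol from estrone, and Fst, the activin-binding follistatin, rose by 1.71 ± 0.20 and 1.63 ± 0.20 on the log2 scale. Itga6, Tmtc1 and Rfx2 fell by 2.42, 2.86 and 2.45, and Rhox8, Psd, Hist1h2ae and Hist1h4d rose by 2.25 to 2.44 on that scale. In the mm10 annotation, Shroom3 (ENSMUSG00000029381) lies on chromosome 5 from 92683435 to 92965318, Ghr (ENSMUSG00000055737) on chromosome 15 from 3317760 to 3583492, Grem1 (ENSMUSG00000074934) on chromosome 2 from 113746164 to 113758646 and Nppc (ENSMUSG00000026241) on chromosome 1 from 86666291 to 86670571. With edgeR, 4924 genes rose and 4714 fell of 18362 tested.

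Among gene lists in granulosa cells, 56 of 64 oxidative phosphorylation genes rose (57 adjusted over the list alone), led by Ndufs4 (log2 1.21 ± 0.14) and Uqcrq (1.28 ± 0.16). Of 20 cholesterol synthesis genes, 17 rose (17 over the list alone), among them Fdps (1.51 ± 0.21). Of 17 steroid hormone synthesis genes 10 rose (10), and of 34 proliferation genes 27 rose (28), among them Mki67 (0.98 ± 0.15) and Cenpf (0.93 ± 0.15). Of 23 granulosa hormone and follicle genes 13 rose and 5 fell (13 and 5). Collagen and extracellular matrix genes fell in 16 and rose in 4 of 39 (16 and 5), and dissociation stress genes fell in 11 and rose in 1 of 26 (9 and 1), among them Egr2 (-1.52 ± 0.23). Camera gave adjusted p values of 2.18e-17 to 0.0207 for these 7 lists, and adjusted p = 0.647 to 0.821 with an estimated correlation. Summed theca markers in granulosa cells were at 1292 ± 423 CPM in acyclic and 454 ± 95.6 in young libraries. Different clusters held most granulosa cells of each group: clusters 3, 7, 10 and 12 held 18.7%, 14.4%, 12.49% and 10.7% of them, pooled, in young mice and 3.6%, 1.5%, 0.9% and 1.5% in acyclic mice, while clusters 0 and 1 went from 12.4% and 10.5% to 31.3% and 29.3%. In the clusters common to both groups 6113 genes were called, and Itga6 (adjusted p = 0.272), Fdx1 (0.116) and the steroid, cholesterol, collagen and follicle lists (adjusted p = 0.0550 to 0.720) no longer passed, while the log2 changes of Shroom3, Grem1, Nppc, Hsd3b1, Hsd17b1, Fst, Tmtc1 and Fdps shrank to -2.14, 1.95, 1.29, 0.80, 0.79, 0.86, -1.83 and 0.88; without acyclic replicates 2 and 3 the stress list did not (0.124). Without acyclic replicate 1 the log2 changes of Ghr and Ccn2 were -4.40 and -5.09.

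**Figure D2:**
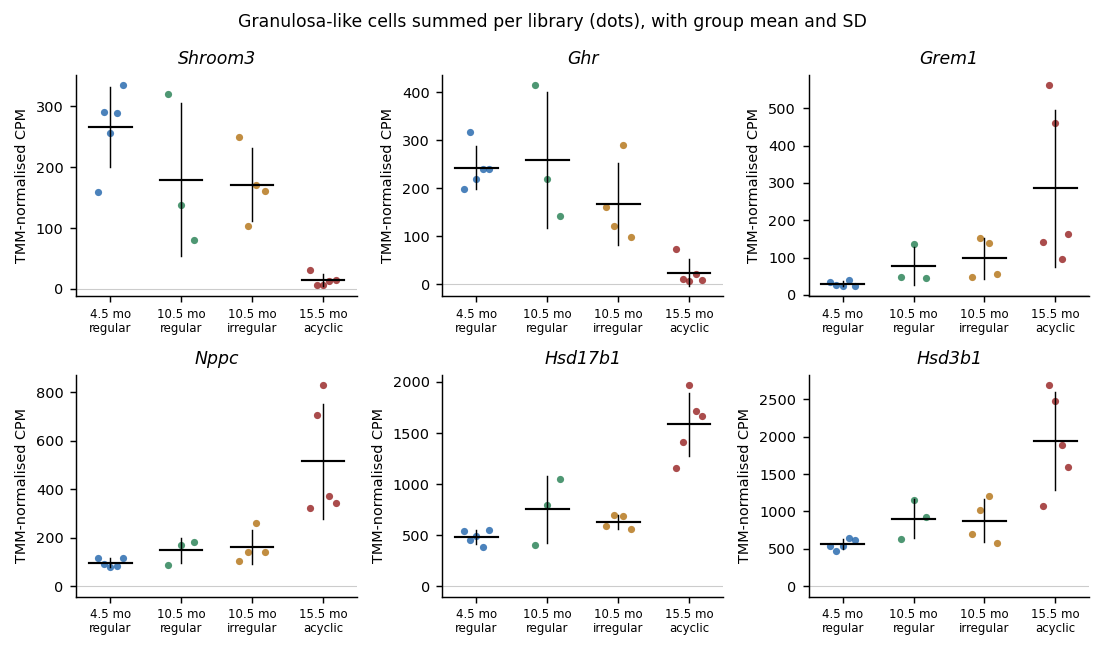
Normalised expression (CPM) of 6 genes summed over the granulosa cells of each library (dots), with the mean and SD of the 4 groups. Shroom3 and Ghr averaged 266 and 242 CPM in young regular and 14.4 and 23.5 in post-estropausal acyclic libraries.

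In luteal cells, acyclic (n = 4) against young (n = 5) mice differed in 2742 of 13927 genes, of which 1372 rose. Prss35, a secreted protease-like protein, rose from 128 ± 12.4 to 640 ± 345 CPM (SD; log2 2.32 ± 0.45, SE; adjusted p = 0.0059 in edgeR), and Egr3, an early growth response transcription factor, fell from 68.5 ± 16.1 to 8.62 CPM (log2 -2.96 ± 0.51). Samd4 fell by 3.10 ± 0.68, and Mgarp and Cst12 rose by 2.04 ± 0.49 and 2.65 ± 0.63 on the log2 scale. Of 64 oxidative phosphorylation genes 41 rose (54 adjusted over the list alone), among them Ndufb4 (1.3 ± 0.19), and of 80 ribosomal protein genes 17 rose (23). Of 17 antigen presentation genes 8 rose (10), among them H2-Aa, a class II chain (log2 3.68 ± 0.84), and Cd74 (3.48 ± 0.79). Of 38 lysosome genes 10 rose and 1 fell (11 and 1), and of 21 interferon response genes 5 rose and 1 fell (11 and 1). Adjusted p values from camera were 1.15e-18 to 0.00709, and adjusted p = 0.647 to 0.801 with an estimated correlation. At resolution 2, where 1701 genes were called, cluster 20 held 736 young and 147 acyclic luteal cells and cluster 24, with close luteal and theca scores, 112 and 611. Summed macrophage markers in luteal cells were at 44.6 ± 40.4 CPM in acyclic and 7.91 in young libraries, and granulosa markers at 2146 ± 698 and 963 ± 228. With a replicate block 960 genes were called, and Mgarp, Cst12, Cd74 and H2-Aa did not pass (adjusted p = 0.0501 to 0.0649); without young regular replicates 2, 3 or 4 the count was 1696, 1769 or 1164, and without acyclic replicates 1 or 4 it was 1310 or 1502. Pik3c2g, Yipf1, Kcnk3, Nav3, Ccn4, Rnf152 and Lrrfip1 were also called, but each lost the call in 5 to 14 alternatives, with adjusted p up to 0.253; without acyclic replicate 1, Pik3c2g, Yipf1, Kcnk3, Cst12 and the luteal interferon list (0.0867) did not pass. Samd4 did not pass at resolution 2 (adjusted p = 0.0598). The log2 changes of Cst12 and H2-Aa were 1.65 and 2.97 without acyclic replicate 1, and those of Samd4 and Egr3 were -3.73 and -4.00 without acyclic replicate 5.

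In theca cells, acyclic against young mice (n = 5 each) differed in 5119 of 14419 genes, of which 2355 rose. Enpep, the aminopeptidase A of the renin-angiotensin system, fell from 42.1 ± 13.1 to 0.569 ± 0.686 CPM (SD; adjusted p = 1.9e-05 in edgeR). Cdkn1a, which encodes the cell cycle inhibitor p21, fell from 62.3 ± 8.51 to 15.7 ± 6.32 CPM (log2 -1.89 ± 0.22, SE; adjusted p = 1.7e-05). Lama2, a laminin chain, fell by 2.86 ± 0.36, and Samd4, B4galt5, Grk5 and Sct by 2.51, 2.35, 2.27 and 3.20. Adh1, an alcohol dehydrogenase, rose from 109 ± 20.5 to 321 ± 215 CPM, and Il31ra, Cdk5rap2, Hist1h4d, Actr3b and Lars2 rose by 1.49 to 2.69 on the log2 scale. Cdkn2a and Cdkn2b did not pass (adjusted p = 0.70 and 0.82). Of 39 collagen and extracellular matrix genes 22 fell (25 adjusted over the list alone), among them Fn1 (-4.31 ± 0.53), Col4a2 (-2.60 ± 0.30), Col1a2 (-3.15 ± 0.38) and Nid1 (-3.47 ± 0.41). Secreted senescence-associated factors fell in 15 and rose in 3 of 46 (15 and 3), among them Icam1 (-2.08 ± 0.40). Of 19 NF-kB genes 6 fell (6), with Nfkb1 at -1.55 ± 0.23, of 26 dissociation stress genes 13 fell (15), of 33 proliferation genes 11 fell and 2 rose (12 and 2), and of 26 p53 targets 8 fell and 1 rose (9 and 1). Of the oxidative phosphorylation genes 29 rose (33). With camera the adjusted p was 3.1e-12 to 0.0347 for these 7 lists, and adjusted p = 0.561 to 0.801 with an estimated correlation. Summed stromal markers in theca cells were at 216 ± 73.8 CPM in acyclic and 699 ± 152 in young libraries. Cluster 16 held 23.1% of theca cells in young and 3.3% in acyclic mice, and cluster 14 held 23.9% and 58.3%; without cluster 16, Col1a2 (adjusted p = 0.90), Nid1 (0.138), Sct (0.514) and the proliferation list (0.640) did not pass, and the log2 changes of Fn1, Lama2 and Col4a2 shrank to -1.88, -1.24 and -1.21. Without acyclic replicate 5 the log2 change of Enpep was -7.19 in place of -5.79, and with doublets kept -4.18. That of Il31ra was 1.71 without acyclic replicates 2 and 3. Il31ra and Lars2 were among the leading genes of the unnamed cluster 24 (median 1884 UMIs), which made up 2.56% of acyclic and 0.357% of young libraries, and Hist1h4d and Lars2 of unnamed cluster 17. The theca p53 list did not pass without acyclic replicate 1 or young regular replicate 1 (adjusted p = 0.0503 and 0.0506).

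In stromal cells, acyclic (n = 4) against young (n = 5) mice differed in 2607 of 14759 genes, of which 1120 rose. Tnfrsf12a, the receptor of the cytokine TWEAK, fell from 85.1 ± 23.3 to 9.82 ± 2.35 CPM (SD; log2 -3.17 ± 0.57, SE; adjusted p = 0.0012 in edgeR). H2-Aa, a class II antigen chain, rose from 3.72 ± 1.11 to 30.4 ± 5.62 CPM, and Gphn, a scaffold protein, from 276 ± 65.7 to 911 ± 81.1 CPM. Gatm, the first enzyme of creatine synthesis, rose from 39.4 to 158 CPM. Cmss1 rose from 1075 ± 675 to 5076 ± 1803 CPM, and Lars2, Cdk8 and Ablim1 by 1.63 to 1.89 on the log2 scale. Cmss1, Gphn and Lars2 also led the unnamed cluster 24, whose cells had a median of 1884 UMIs and made up 2.56% ± 1.65 of acyclic and 0.357% of young libraries, and Cdk8 was among the leading genes of unnamed cluster 17 (median 2263 UMIs). Of 34 proliferation genes 29 fell (33 adjusted over the list alone), among them Cenpe (-3.02 ± 0.37), Cdc20 (-3.18 ± 0.39), Ube2c, Prc1 and Tpx2. Of 18 antigen presentation genes 7 rose (8), of 38 lysosome genes 6 rose and 3 fell (9 and 3), with Ctsh at 1.53 ± 0.22, of 23 follicle genes 8 rose (10), and of 18 lipid-laden macrophage genes 3 rose (5). Camera gave adjusted p values of 5.88e-55 to 0.0328, and adjusted p = 0.26 to 0.817 with an estimated correlation. Class II genes were highest in dendritic cells, summed macrophage markers in stromal cells were at 37.6 against 18.3 CPM, and granulosa markers at 1075 ± 1021 against 328 ± 19.5. Cluster 22 held 13% of stromal cells in young and 1.9% in acyclic mice and cluster 4 held 45.1% and 75.9%; without cluster 22, Cdc20, Cenpe, Prc1, Tpx2 and Ube2c (adjusted p = 0.160 to 0.988) and the lysosome and lipid-laden lists (0.253 and 0.127) did not pass, while Hmmr (-3.15 with it, -3.80 without acyclic replicate 5) was at 0.53. At resolution 2 the log2 change of Tnfrsf12a was -1.92. Without acyclic replicate 1 the count was 1694, and without acyclic replicate 4, Cdk8 (adjusted p = 0.0535), Inhbb (0.63), Hsd17b1 (0.43) and the follicle and lipid-laden lists (0.122 and 0.062) did not pass; without acyclic replicate 1 the lysosome and lipid-laden lists did not (0.254 and 0.466).

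In endothelial cells, acyclic (n = 3) against young (n = 5) mice differed in 1069 of 12910 genes, of which 461 rose. Fabp4, a fatty acid carrier of capillary endothelium, rose from 5.49 ± 6.76 to 1018 ± 435 CPM (SD; log2 7.44 ± 0.86, SE; adjusted p = 0.0024 in edgeR). Fabp4 (ENSMUSG00000062515) lies on chromosome 3 from 10204088 to 10208576. Plvap, a protein of fenestrated endothelium, and Gpihbp1, which carries lipoprotein lipase to the capillary lumen, rose by 1.77 ± 0.40 and 1.63 ± 0.36 on the log2 scale. Fabp4, Plvap and Gpihbp1 also lead endothelial cluster 37 of resolution 2, which held 41 young and 32 acyclic cells, beside 948 and 203 in the other endothelial cluster (11). Adamts4, a matrix protease, fell from 157 to 33.9 CPM, Csf2rb, a cytokine receptor chain, from 100.1 to 21.4 CPM and Nup210l from 132 to 25.8 CPM. Cdkn2b, which encodes the cell cycle inhibitor p15, rose from 2.64 ± 0.852 to 8.99 ± 3.85 CPM (adjusted p = 0.018), and Cdkn2a did not pass (0.051). Of 16 steroid hormone synthesis genes 7 rose (8, with 1 lower, adjusted over the list alone), with Cyp11a1 from 67.7 to 638 CPM, and of 15 lipid-laden macrophage genes 8 rose (9, with 1 lower), with Trem2 at 19.1 against 0.222 CPM. Of 37 lysosome genes 4 rose (6), of 19 cholesterol genes 2 rose (5), and 4 oxidative phosphorylation genes rose (11). The NF-kB list was lower, with 5 of 21 genes lower and 1 higher (8 and 2), as were the stress list, with 1 of 26 lower (0), and the interferon list of 28 genes, with 1 higher (2, with 4 lower). Adjusted p values from camera were 3.18e-07 to 0.0482 for these 8 lists, and adjusted p = 0.561 to 0.823 with an estimated correlation. Cyp11a1 and Trem2 were highest in other classes, and within endothelial cells summed theca markers were at 892 ± 510 against 135 ± 48.9 CPM and macrophage markers at 589 ± 591 against 27.8 ± 6.97. With a replicate block 557 genes were called, and without young regular replicates 3 or 4, or acyclic replicates 1 or 5, 642, 502, 668 or 707; Cdkn2b, Plvap, Gpihbp1, Hist1h1e, Rsad2, Btnl9, Nlgn1, Sh3gl3 and Cadm1 lost the call in at least 1 alternative (adjusted p up to 0.175), Cdkn2b without acyclic replicates 4 or 5. The log2 change of Fabp4 was 8.52 without young regular replicate 5, that of Csf2rb -2.87 in place of -2.19 and of Trem2 4.44 in place of 6.27 without acyclic replicate 1, and that of Cyp11a1 2.64 in place of 3.24 without acyclic replicate 4; with doublets kept Cyp11a1 was at 1.71 and Trem2 at 4.72. Of the endothelial lists, without acyclic replicate 4 cholesterol, stress, NF-kB and interferon did not pass (adjusted p = 0.0896 to 0.708), without replicate 5 NF-kB and interferon (0.389 and 0.192), without replicate 1 lysosome (0.139), and without young regular replicates 3, 4 or 5 interferon, interferon or stress (0.0596, 0.128 and 0.0905).

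In macrophages, acyclic against young mice (n = 5 each) differed in 31 of 9289 genes, of which 14 rose, and 1566 had an unadjusted p under 0.05. Mpp7, a cell polarity scaffold, fell from 230 ± 64.0 to 66.6 ± 28.9 CPM (SD; log2 -1.77 ± 0.29, SE; adjusted p = 0.014 in edgeR). Man1a, Sik3 and Itgav, an integrin chain, fell by 1.63 ± 0.25, 1.52 ± 0.25 and 1.31 ± 0.22. Hmox1, which degrades heme, rose by 3.58 ± 0.75, and Creb5 and Nfkb1 fell by 1.44 and 1.36. Of 18 antigen presentation genes 0 fell (13 adjusted over the list alone; edgeR), of 23 NF-kB genes 1 fell (7) and of 44 secreted senescence-associated factors 0 changed (10 fell and 1 rose). Oxidative phosphorylation genes rose in 0 of 64 (26), ribosomal protein genes in 0 of 80 (5), cholesterol genes in 0 of 16 (3, with 1 lower), steroid genes in 2 of 12 (10) and follicle genes in 3 of 20 (11), and interferon and proliferation genes were lower as lists with 0 members called (0). With camera the adjusted p was 1.36e-14 to 0.00606 for these 10 lists, and adjusted p = 0.26 to 0.821 with an estimated correlation. Summed granulosa markers in macrophages were at 2246 ± 2461 CPM in acyclic and 251 ± 182 in young libraries, beside called rises of Hsd17b1 and Fst. The count was 0 without young regular replicate 5 and without acyclic replicates 2 and 3, 99 or 251 without acyclic replicates 2 or 5, 8 to 18 without any other library but acyclic replicate 1, and 330 with DESeq2. Mpp7, Man1a, Sik3 and Itgav lost the call without young regular replicate 5 (adjusted p = 0.0536 to 0.0569), and Hmox1, Creb5, Nfkb1, Hsd17b1 and Fst in 6 to 11 alternatives (up to 0.279), with the log2 change of Hmox1 at 2.98 without acyclic replicate 3 and at 1.14 without both acyclic replicates 2 and 3; the macrophage proliferation list did not pass without acyclic replicate 5 (0.459), young regular replicate 4 (0.0628), or acyclic replicates 2 and 3 (0.153).

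In T cells, acyclic (n = 5) against young (n = 3) mice differed in 54 of 3946 genes, of which 9 rose. Ccl1, a chemokine made by activated T cells, was at 204 ± 173 CPM (SD) in young and 0.404 ± 0.904 in acyclic libraries (adjusted p = 0.0015 in edgeR). Slc16a10, an aromatic amino acid transporter, fell from 265 ± 83.0 to 23.6 ± 21.6 CPM (log2 -2.94 ± 0.37, SE; adjusted p = 0.00027), and Spag9 and Serpinb9, an inhibitor of granzyme B, by 1.78 ± 0.27 and 1.99 ± 0.31. Nr4a1, an early gene of T cell receptor signalling, fell by 1.68 ± 0.31. BE692007 rose from 77.4 to 280 CPM, and Txnip, an inhibitor of thioredoxin, from 274 ± 8.29 to 597 ± 157 CPM. Cdkn1a was at 69.1 ± 35.6 CPM in young and 10.6 ± 7.02 in acyclic libraries (adjusted p = 0.015). Of 18 proliferation genes 3 fell (6 adjusted over the list alone), of 11 NF-kB genes 1 fell (2), of 79 ribosomal protein genes 1 rose (4) and of 61 oxidative phosphorylation genes 0 rose (0). Camera gave adjusted p values of 2.0e-07 to 0.0255, and adjusted p = 0.561 to 0.801 with an estimated correlation. The count was 16, 10, 31 or 29 without young regular replicates 3 or 5 or acyclic replicates 2 or 3, 152 without a filter, and 9 without both acyclic replicates 2 and 3, where Cdkn1a (adjusted p = 0.0703) and the NF-kB list did not pass; that list was also lost without young regular replicate 3, without acyclic replicate 3 and with a replicate block. Without acyclic replicate 5 the log2 changes of Slc16a10 and Ccl1 were -4.13 and -8.01 (-6.92 with it for Ccl1). Txnip and Gphn lost the call without young regular replicates 3 or 5, Nr4a1 without replicate 3, Serpinb9 with doublets kept, and Rasgef1b, Epha3, Chordc1, Gadd45b, Nusap1 and Birc5 in 5 to 11 alternatives (adjusted p up to 0.303).

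Age with regular cycles was addressed by peri-estropausal regular (n = 3) against young regular mice (n = 5). In granulosa cells 3 genes rose and 0 fell with edgeR; 1044 had an unadjusted p under 0.05, and DESeq2 called 16. Luzp4 rose from 0.183 to 4.62 CPM (log2 4.66 ± 0.39, SE; adjusted p = 1.4e-05); Gm15127 was at 0.0294 and 0.954 CPM and Gm10439 at 0.0363 and 0.357 CPM. These 3 lie outside the rule for named genes and were chosen after their values were seen; Gm15127 did not pass with the 2 groups fitted alone (adjusted p = 0.095) and Gm10439 did not in 12 alternatives (up to 0.816). Without peri-estropausal regular replicate 1 the count was 10. In stromal cells edgeR called 0 genes (1296 at unadjusted p under 0.05; DESeq2 58; 1, 3, 6, 8 and 1 without young regular replicates 2 and 4 and peri-estropausal regular replicates 1, 2 and 3), and in macrophages 0 (215; DESeq2 0). In granulosa cells the lysosome, steroid, antigen presentation, oxidative phosphorylation, ribosomal, proliferation and follicle lists were higher and the stress and p53 lists lower. In stromal cells the lysosome, antigen presentation, follicle and T cell effector lists were higher and the cholesterol, stress and proliferation lists lower. In macrophages oxidative phosphorylation and ribosomal genes were higher and secreted senescence-associated factors, interferon and proliferation genes lower. Adjusted p values from camera were 1.13e-16 to 0.0435 for these 21 lists, and adjusted p = 0.425 to 0.876 with an estimated correlation. Over all genes 0 members were called; adjusted over the list alone, follicle genes in stromal cells (12 higher), antigen presentation genes there (5 higher) and T cell effector genes there (2 of 5 higher) had the most. Summed granulosa markers in stromal cells were at 998 ± 1057 CPM in peri-estropausal regular and 328 ± 19.5 in young libraries (SD), and epithelial markers at 42.2 ± 16.2 and 11.7 ± 2.37.

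Cycle regularity at 10.5 months was addressed by irregular (n = 4) against regular mice (n = 3). EdgeR called 0 genes in granulosa cells (820 at unadjusted p under 0.05; DESeq2 1), 0 in stromal cells (542; DESeq2 1; 1 without regular replicate 3) and 0 in macrophages (222; DESeq2 0). In granulosa cells the oxidative phosphorylation, ribosomal, interferon and proliferation lists were lower. In stromal cells the oxidative phosphorylation, ribosomal, proliferation and follicle lists were lower and the interferon and NF-kB lists higher. In macrophages the antigen presentation, oxidative phosphorylation and ribosomal lists were lower and the proliferation list higher. With camera the adjusted p was 4.19e-25 to 0.0451, and adjusted p = 0.647 to 0.823 with an estimated correlation. No list member was called over all genes, and 3 follicle genes in stromal cells were lower adjusted over the list alone, where summed granulosa markers were at 426 ± 58.7 CPM in irregular and 998 ± 1057 (SD, n = 3) in regular libraries. Of the macrophages, 143 of 515 irregular and 0 of 246 regular cells were in cluster 36. With the replicate number as a block edgeR called 0, 1 and 0 genes in granulosa, stromal and macrophage cells (615, 324 and 129 at unadjusted p under 0.05), the stromal interferon and macrophage oxidative phosphorylation lists did not pass camera (adjusted p = 0.721 and 0.104), and 6 further lists did: p53 targets in granulosa cells, steroid and stress genes in stromal cells, and interferon, NF-kB and lipid-laden genes in macrophages (0.00142 to 0.0473).

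The loss of cycles, with 5 further months of age, was addressed by acyclic against irregular mice. In granulosa cells (n = 5 and 4) 4389 genes rose and 4569 fell with edgeR. Shroom3 fell from 171 ± 60.3 to 14.4 CPM (SD; log2 -3.55 ± 0.45, SE), Ghr by 2.81 ± 0.58, Ccn2 by 2.79 ± 0.69 and Rfx2 by 2.43 ± 0.37. Nppc rose from 163 ± 68.8 to 515 CPM (log2 1.66 ± 0.32), Lhcgr, the LH receptor, by 2.62 ± 0.62, and Hist1h1e, Hist1h3e and Tmsb15b2 by 1.69 to 1.89. Of the oxidative phosphorylation genes 60 rose (61 adjusted over the list alone), of cholesterol genes 15 (16), of proliferation genes 29 (31) and of steroid genes 9 (9), with Hsd17b1 at 1.32 ± 0.22. Collagen genes fell in 14 and rose in 2, stress genes fell in 9 (Klf4, -1.55 ± 0.27), NF-kB genes fell in 8 and rose in 1, and secreted senescence-associated factors fell in 20 and rose in 6 of 50. Camera gave adjusted p values of 5.79e-24 to 0.0482 for these 8 lists, and adjusted p = 0.647 to 0.823 with an estimated correlation. In the clusters common to both groups the log2 change of Shroom3 was -1.23, and Fdx1 (adjusted p = 0.0547) and the steroid, collagen and secreted-factor lists (0.0819 to 0.299) did not pass, and without acyclic replicates 2 and 3 the secreted-factor, steroid, NF-kB and stress lists did not (0.0888 to 0.195) and Lhcgr was at 1.71 (3.80 with cluster 15 counted as granulosa). In granulosa cells the NF-kB list did not pass without irregular replicates 1 or 4 or acyclic replicates 2, 3 or 5 (0.0506 to 0.0942), the stress list without irregular replicates 1 or 3 or acyclic replicate 2 (0.0541 to 0.0677), and the secreted-factor list without irregular replicate 4 or acyclic replicate 3 (0.0675 and 0.056); without acyclic replicate 1 the log2 changes of Ghr and Ccn2 were -3.87 and -4.49, and without irregular replicate 3 that of Ccn2 was -2.16.

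In stromal cells (n = 4 each) 569 genes rose and 1003 fell from irregular to acyclic. Tnfrsf12a fell by 2.78 ± 0.59 (SE, log2; 1.44 at resolution 2), and Nup210l, a nucleoporin, from 232 ± 33.1 to 35.3 ± 15.4 CPM (SD). Gphn, Cmss1, Cdk8 and Lars2 rose by 1.73 ± 0.18, 2.09 ± 0.48, 2.12 ± 0.55 and 2.35 ± 0.47. Of 34 proliferation genes 24 fell (28 adjusted over the list alone), among them Cenpe (-2.58 ± 0.38), and of 21 NF-kB genes 3 fell, with Nfkb1 at -1.50 ± 0.32. Lysosome genes rose in 3 and fell in 1, antigen presentation genes rose in 3 (4), and oxidative phosphorylation genes, with 1 higher and 1 lower (0), passed as a list. Adjusted p values from camera were 8.78e-39 to 0.0361, and adjusted p = 0.425 to 0.821 with an estimated correlation. In macrophages (n = 5 and 4) 1 gene rose and 21 fell, and 1700 had an unadjusted p under 0.05. Mpp7 fell by 2.0 ± 0.30 (adjusted p = 0.013), Myo1e, an unconventional myosin, by 2.12 ± 0.35, Ankrd28 by 1.75 ± 0.29 and Sik3 by 1.67 ± 0.26. Macrophage cluster 36 held 143 irregular cells, 114 of them from replicate 4, and 8 acyclic cells, and Myo1e was highest in irregular replicate 4 (715 CPM), without which its log2 change was -1.49. The steroid, cholesterol, oxidative phosphorylation, ribosomal and follicle lists were higher (0 members over all genes; 7, 3, 29, 1 and 11 over the list alone) and the antigen presentation, NF-kB and lipid-laden lists lower (0, 1 and 0; 0, 1 and 3), with adjusted p of 1.96e-14 to 0.0394, and adjusted p = 0.647 to 0.821 with an estimated correlation. In these macrophages summed granulosa markers were at 2246 ± 2461 CPM in acyclic and 272 ± 45.1 in irregular libraries, and theca markers at 655 ± 742 and 186 ± 103. Without stromal cluster 22 the proliferation, antigen presentation and lysosome lists did not pass (adjusted p = 0.0946 to 0.854), and Cenpe, Hmmr and Prc1 were at 0.13, 0.61 and 0.095; the stromal count was 860 or 724 without acyclic replicates 1 or 5. The macrophage count was 10, 118, 6, 2, 44, 9, 3 or 317 without irregular replicates 1, 3 or 4 or acyclic replicates 1, 2, 3, 4 or 5, Mpp7 did not pass with the 2 groups alone (0.113), and Sik3, Myo1e, Ankrd28 and Nfkb1 did not in 3 to 7 alternatives (up to 0.234), and Cdk8 in stromal cells did not without irregular replicate 1 (0.0566). Of the stromal lists, antigen presentation did not pass without irregular replicates 1 or 2, NF-kB without irregular replicates 3 or 4 or acyclic replicates 4 or 5, lysosome without irregular replicates 2 or 4 or acyclic replicates 1 or 4, and oxidative phosphorylation without irregular replicate 4 (0.0539 to 0.459). Of the macrophage lists, antigen presentation did not pass without acyclic replicate 2, NF-kB without acyclic replicate 2 or irregular replicate 4, lipid-laden genes without acyclic replicates 4 or 5 or irregular replicates 2 or 3, and ribosomal genes without irregular replicate 4 (0.0515 to 0.802).

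Over all classes and comparisons, 102 of 262 list tests passed with camera, 0 with an estimated correlation and 33 with fry, which asks whether a list's genes move one way. Oxidative phosphorylation passed in 14 of 16 tests and proliferation in 13 of 16. Senescence regulators, a list of cell cycle inhibitors and related genes, passed in 0 of 15 tests (edgeR members: 6 lower and 1 higher of 15 in granulosa and 6 lower and 2 higher in theca cells, adjusted p = 0.167 and 0.0639). T cell effector and exhaustion genes passed in 1 of 10. Ribosomal proteins passed in 9, antigen presentation and NF-kB in 8 each, follicle genes in 7, the lysosome, interferon and stress lists in 6 of 16 each, secreted factors in 4, lipid-laden genes in 3 and p53 targets in 2 of 16; cholesterol and steroid lists passed in 6 of 15 each and collagen in 3 of 15.

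**Figure D3:**
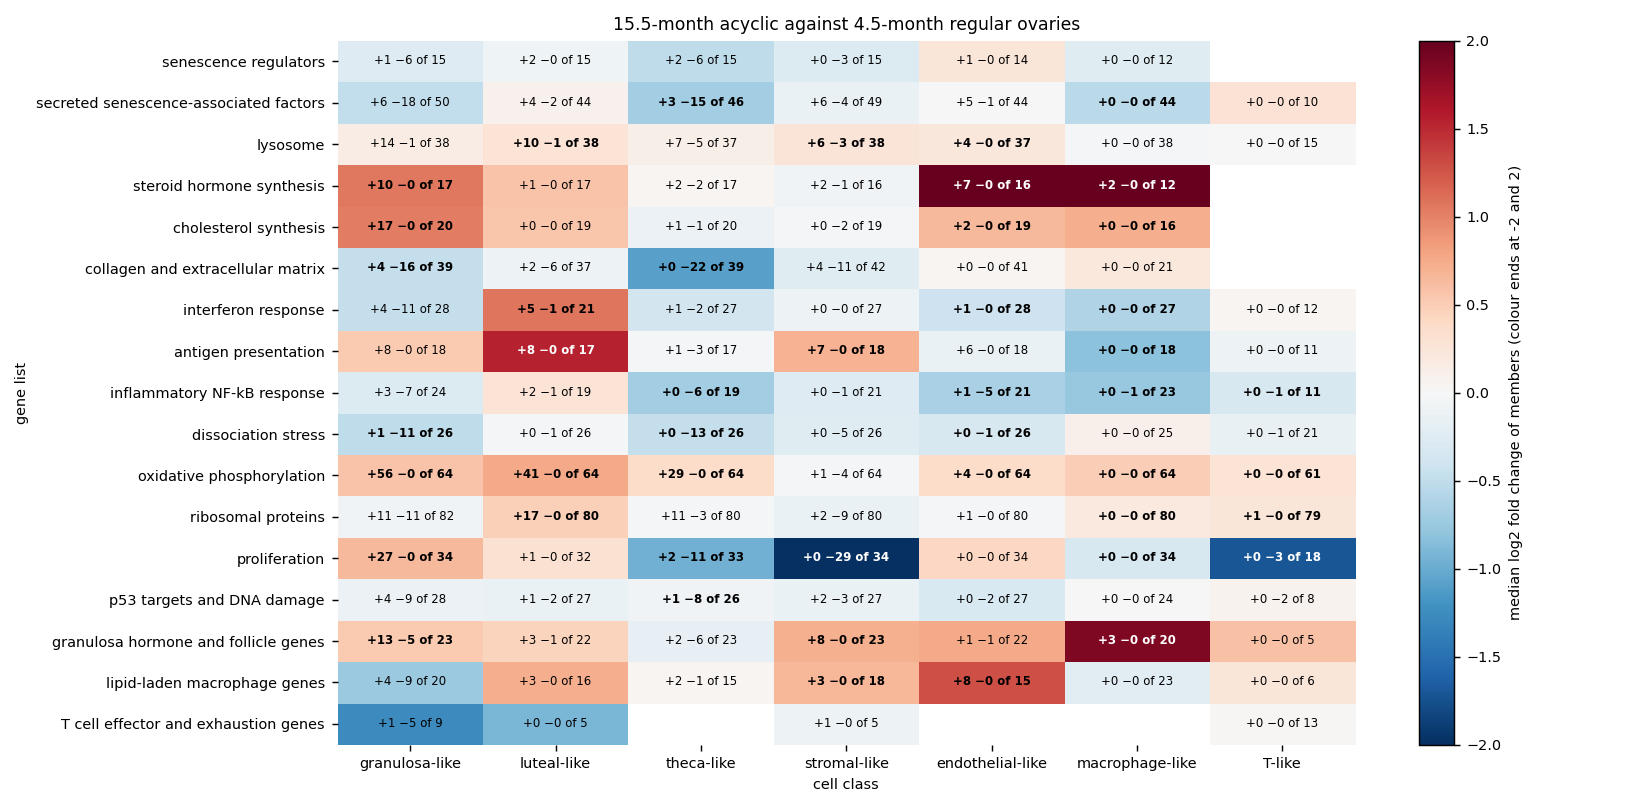
Median log2 fold change of the members of 17 gene lists (colour, from -2 to 2) in 7 cell classes, post-estropausal acyclic against young regular, with the members that rose (+) and fell (-) of those tested; bold marks lists that passed. Senescence regulators passed in none of the classes.

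Whole libraries were compared for Cdkn2a and Cdkn1a, which encode the senescence-associated inhibitors p16 and p21. Cdkn2a was at 2.02 ± 0.170 CPM (SD, n = 5) in young regular, 2.41 ± 1.31 (n = 3) in peri-estropausal regular, 3.61 ± 2.78 (n = 4) in irregular and 0.725 ± 0.776 CPM (n = 5) in acyclic libraries. On the log2 scale acyclic libraries differed by -0.91 from young and by -1.35 from irregular ones (exact two-sided permutation p = 0.0317 each, adjusted 0.127), and by -1.82 and -2.37 with a pseudocount of 0.1 CPM in place of 1 (adjusted p unchanged). Cdkn1a was at 61.6 ± 7.65, 47.7 ± 13.5, 61.7 ± 20.9 and 59.5 ± 40.5 CPM in the same order, and acyclic differed from young libraries by -0.24 (exact permutation p = 0.548). None of the 8 comparisons passed. Within classes not given above, changes from young to acyclic did not pass in edgeR: Cdkn2a in granulosa (-2.02 ± 0.86 on the log2 scale, SE), luteal (-1.77 ± 1.02) and stromal cells (0.30 ± 0.39), Cdkn2b in the same classes (0.49 ± 0.37, -1.02 ± 0.71 and 0.93 ± 0.37), and Cdkn1a in these (0.29 ± 0.36, -0.95 ± 0.48 and -1.21 ± 0.53), in macrophages (-0.70 ± 0.23) and in endothelial cells (-0.34 ± 0.34), with adjusted p of 0.0576 to 0.649. Alternatives brought adjusted p values under 0.05 for Cdkn2a in granulosa (down to 0.0115, without acyclic replicate 2) and endothelial cells (0.0226, DESeq2), Cdkn2b in granulosa cells (0.0263, with cluster 15 counted as granulosa), and Cdkn1a in luteal (0.0474, without acyclic replicate 5) and stromal cells (0.0258, with the 2 groups alone). The filter on low counts left out Cdkn2a and Cdkn2b in macrophages and T cells. Irregular replicate 4 had 7.64 CPM of Cdkn2a and 114 cells of macrophage cluster 36, where Cdkn2a was high. Whole-library values mix class shares with expression within classes. Smooth muscle or pericyte cluster 18, also high in Cdkn2a, made up 1.43% to 2.80% of young libraries. In acyclic replicates 1 to 5 it made up 0.467%, 0.127%, 0.0553%, 0.979% and 1.77%, beside 0.383, 0.177, 0.175, 0.872 and 2.02 CPM of Cdkn2a. Cell mix and expression per cell cannot be told apart in the whole-library values. Cdkn2a (ENSMUSG00000044303) lies on chromosome 4 from 89274471 to 89294653 and Cdkn1a (ENSMUSG00000023067) on chromosome 17 from 29090976 to 29100727.

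The sorted library addressed which cells have a high signal of SPiDER-βGal after estropause. Theca cells made up 32.0% of its 4751 kept cells (exact 95% interval 30.6 to 33.3), against 6.79% ± 4.45 (SD, n = 5) and at most 13.5% in acyclic libraries. Stromal cells made up 22.4% (21.3 to 23.7), against at most 4.39%, macrophages 7.79% (7.04 to 8.59), against at most 2.90%, and smooth muscle or pericyte cells 3.12% (2.64 to 3.65), against at most 1.93%. Lymphatic endothelial cells, at 1.24% (0.947 to 1.60), also lay above every acyclic library, as did dendritic (0.884%) and mast cells (0.253%), and B cells (0.147%) lay below; with the sorted cells clustered on their own no cluster took these 3 names. Granulosa cells made up 12.503% (11.6 to 13.5), against at least 23%, epithelial cells 1.31% (1.00 to 1.67), against at least 3.24% (but 3.62% with the sorted cells clustered on their own), and T cells 0.0421%, against at least 0.911%. NK cells, neutrophils and oocyte-like cells had 0 cells, which allows up to 0.0631% each. Luteal (7.09%), endothelial (1.81%) and all immune cells (9.11%) lay within the range of acyclic libraries. The sort, digestion and software version differ together from the unsorted libraries, there is no replicate, and intervals cover counting error only.

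**Figure D4:**
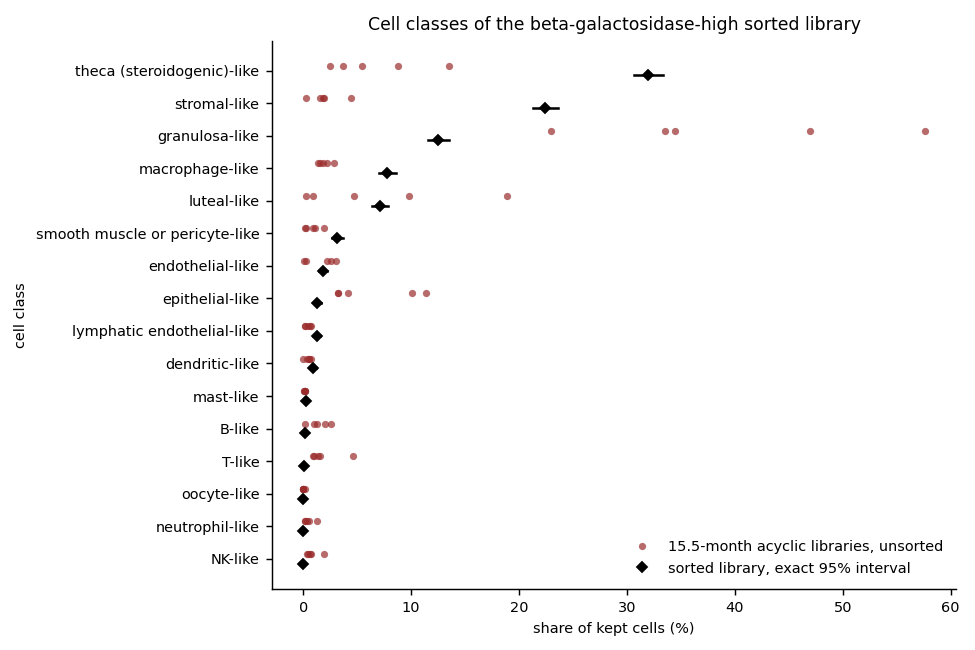
Share of kept cells (%) of 16 classes in the 5 post-estropausal acyclic libraries (dots) and in the sorted library (diamonds, exact 95% interval). Theca and stromal cells made up 32.0% and 22.4% of the sorted library.

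Within classes, sorted cells were set against acyclic libraries without a test. Cdkn1a in theca cells was at 130 CPM (122 to 138) in sorted cells and 15.6 ± 6.12 CPM (SD, n = 5) in acyclic libraries (log2 3.06). In macrophages it was at 472 against 157 ± 50.5 CPM (log2 1.66), in stromal cells at 90.1 against 37.3 ± 35.5 (1.70), in granulosa cells at 62.2 against 29 ± 21 (1.33), and in luteal cells at 45.8 against 121 ± 85.2 CPM (-1.08). Cdkn2a in macrophages had 30 counts, 19.3 CPM (13 to 27.5), against 2.49 ± 3.81 CPM (log2 3.23), and in theca cells 35 counts (log2 1.44); it had 0 counts in granulosa and epithelial cells. Glb1, which encodes beta-galactosidase, was lower in all 8 classes (log2 -0.71 to -2.51). Random gene lists were mostly lower too, and Glb1 was not tested against that shift. Tnfrsf12a in stromal cells was at 205 CPM (192 to 219) against 10.5 ± 3.01, and Tnnt2, cardiac troponin T, at 116 against 11.2 ± 18.3 CPM (n = 3, 14 counts in all, from 0 to 32.3 CPM) in smooth muscle or pericyte cells, where the log2 ratio of 4.82 went from 3.79 to 6.32 with 1 acyclic library left out. Usp50, Wdr89, Nutf2-ps1, Eno1b, Bc1, Tmem254a, Bloc1s1, Ftl1-ps1 and Plac9a were among the highest ratios, and Camk1d, Cmss1, Cdk8, Gphn, Il31ra, Grm7 and Hist1h2ap among the lowest. Across all 8 classes, 18 genes were higher and 39 lower in each.

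Median log2 ratios of senescence regulators ranked high among 10000 random lists in granulosa (percentile 100, median 0.53), theca (100, 0.65), macrophage (99.9, 0.14, 8 members higher and 7 lower), stromal (99.6, -0.003, 7 and 7) and endothelial cells (99.3, 0.31, 8 and 7), and at 93.5, 86.4 and 50.4 in epithelial, smooth muscle and luteal cells. For this list the random lists had medians below 0 in every class (-0.711 in stromal cells), so a high rank is not a rise by itself; for ribosomal genes they were above 0 in most classes (0.266 in endothelial cells). Secreted senescence-associated factors ranked at 100 in granulosa, theca, stromal and macrophage cells (macrophage median -0.17) and at 9.1 in luteal cells. Antigen presentation ranked at 100 in granulosa, macrophage (0.89), smooth muscle, stromal and theca cells (0.69) and at 9.7 in luteal cells. Interferon genes ranked at 100 in macrophage, smooth muscle, stromal and theca cells and at 15.0 in luteal cells, and NF-kB genes at 100 in granulosa, macrophage and theca cells and at 0.2 in luteal cells (median -1.10). Follicle genes ranked at 0 to 1.8 in all 8 classes, with medians from -2.95 to -0.98. Steroid genes ranked at 0 in endothelial and macrophage cells, collagen genes at 0 in endothelial and luteal cells, and proliferation genes at 100 in stromal and endothelial, 99.9 in epithelial and 0 in granulosa and macrophage cells. Ribosomal genes ranked at 100 in 5 classes and at 0.16 in epithelial cells (27 members higher and 53 lower), oxidative phosphorylation at 1.5 in macrophages and 93.7 to 100 elsewhere, and stress genes at 100 in granulosa and 0 in luteal cells. Lysosome genes ranked at 49.6 to 100, p53 targets at 63.0 to 100 and cholesterol genes at 52.2 to 100; lipid-laden genes ranked at 100 in theca and 0.6 in endothelial cells, and T cell effector genes at 91.3 in macrophages and 29.8 in endothelial cells.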

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

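Among the tests in this part, those on looser barcode limits, on smooth muscle and endothelial shares of a part, and on intronic length were chosen after the result was seen.

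Of 329 values checked, 35 lay far from the other libraries of their group by Dixon's criterion, where chance alone gives 16.45. Post-estropausal acyclic replicate 5 had 8 of them, replicate 4 had 6, replicate 1 had 5 and irregular replicate 4 had 5. The values that follow are each the highest of the group unless called lowest, with the nearest other library in brackets, and gene values are CPM of summed counts. Acyclic replicate 1 had 4501 kept cells (2482), and acyclic replicate 4 a median of 25443 UMIs (16953). NK and T cells made up 1.93% (0.685) and 4.59% (1.55) of acyclic replicate 5. Endothelial and mast cells made up 11.0% (3.99) and 4.27% (0.117) of irregular replicate 4. Oocyte-like cells made up 20.6% (0.982) of young regular replicate 2 and 0.147% (0.0222) of acyclic replicate 4. Cdkn1a in whole libraries was at 92.8 (52.9) in irregular replicate 4 and 129.9 (55.1) in acyclic replicate 2.

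In granulosa cells, Ghr and Ccn2 were at 67.2 (19.7) and 31.8 (4.33) in acyclic replicate 1, Tmtc1 at 26.2 (11.0) in acyclic replicate 5, Rfx2 at 14.2 (7.36) in acyclic replicate 4, and Uqcrq lowest at 300.7 (355) in young regular replicate 4. In luteal cells, Pik3c2g and Yipf1 were at 296 (44.7) and 387 (118) in acyclic replicate 1, Nav3, Ccn4 and Rnf152 at 59.7 (6.16), 53.8 (2.15) and 87.7 (14.5) in acyclic replicate 5, and Samd4 at 307 (180.2) in young regular replicate 4. In theca cells, Cdk5rap2 was lowest at 41.9 (57.2) in young regular replicate 2 and Adh1 was at 697 (266) in acyclic replicate 2. In stromal cells, Inhbb, Hsd17b1 and Nup210l were at 235 (13.6), 224 (30.6) and 62.7 (30.6) in acyclic replicate 4, Tnfrsf12a and Nfkb1 were lowest at 23.2 (79.4) and 191 (445) in irregular replicate 2, and Gphn was at 327 (266) in irregular replicate 4. In endothelial cells, Fabp4 was at 16.2 (5.28) in young regular replicate 5. In macrophages, Man1a was lowest at 59.7 (126) in acyclic replicate 3, Hsd17b1 was at 23.2 (7.57) in young regular replicate 1 and Myo1e at 715 (259) in irregular replicate 4. In T cells of acyclic replicate 5, Ccl1 and Slc16a10 were at 1.73 (0) and 52.0 (17.5).

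Between acyclic and young mice, 117 genes fell and 25 rose in all 5 of granulosa, luteal, theca, stromal and endothelial cells, of 11721 tested, where independent classes would share 0.347 and 0.175. The median correlation of changes between classes was 0.413, above the median of 0.214 but not the highest of 0.464 over 125 other splits of the libraries. Free granulosa RNA is argued against, since in the other 4 classes the falling genes held 1.11 times their granulosa CPM in young mice (quartiles 0.882 to 1.75) and the rising genes 1.11 times in acyclic mice (0.842 to 1.21). A length or intron trend is argued against as the whole cause, since 0.863 of the change was left without it. The falling genes were nevertheless long, with a median span of 68561 bases, and the rising ones short, at 4167 bases, against 25451 for all genes. A part due to length therefore stays open. Handling or library day stays open and cannot be told apart from the groups, because no day is given; 0 genes of the stress list were among the falling ones, but the early-response genes Fosl1, Egr3, Maff and Csrnp1 were. Age and loss of cycles may also account for the pattern and were untested.

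Stromal, smooth muscle and endothelial shares were lower in acyclic libraries. Filling by classes outside the stromal, smooth muscle, endothelial, theca and immune part is argued against for stromal cells. These held 10.0% ± 4.52 of it in acyclic and 32.1% ± 4.59 in young libraries (exact p = 0.00794). Smooth muscle or pericyte cells held 4.22% ± 2.32 and 9.83% ± 2.56 (exact p = 0.0159), and endothelial cells 7.93% ± 6.71 and 12.2% ± 3.64 (exact p = 0.246), for which it stays open. Filling by immune cells, inside that part, stays open. The barcode limits cannot be told apart: 0.965 of the stromal difference was left with looser ones, but of the 7951 acyclic barcodes these let in, 6805 had no class name and 13 were stromal, so the share could hardly move. A lower yield on digestion cannot be told apart from fewer cells, as only digested cells were counted (266 stromal in acyclic, 2852 in young libraries). A loss of these cells with age may also account for it and was untested.

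In every class compared, 18 genes were higher and 39 lower in the sorted library than in acyclic libraries. Another annotation may explain part of the higher genes: 22.2% of them overlap another gene's exon, 8.89 times the share of all 5080 genes compared. Fewer intronic reads may explain the lower genes, whose median intronic length was 13.1 times that of all genes. Fewer UMIs per cell cannot be told apart, since 0.778 of the higher genes were left with the summed counts of each class thinned to the same depth, between the bounds set for each outcome, and UMIs per cell were not matched. A difference due to the sort itself was untested, as the sort and the software version changed together.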

How the results depend on the processing

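Alternatives on looser barcode limits, cluster 15, named classes only, clusters in both groups and acyclic replicates 2 and 3 were chosen after the data were seen; the others were planned. Of 172 named genes followed, 158 were called, and 90 of these passed under every alternative run for them. Counts of called genes in granulosa and theca cells between acyclic and young mice stayed within 1.5 times under all alternatives but granulosa clusters in both groups (6113); with 1 library left out they ranged from 8361 to 9522 and from 4119 to 5082. A minimum of 50 cells gave no value for T and endothelial cells, nor for the macrophage and stromal comparisons with acyclic mice. The cause of the changes below was not tested unless fewer libraries, cells or tests made them.

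Shares: between acyclic and young mice 6 classes passed, 3 over cells other than granulosa and luteal, 3 with looser barcode limits, 0 with a replicate block, which 5 pairs cannot pass, and 0 to 7 with 1 library left out. Between acyclic and irregular mice 3 passed, 0 over cells other than granulosa and luteal, 0 on the log2 scale, 0 with a replicate block and 0 with 1 library left out, where the design is too small to pass. The immune total differed by 3.35, by 5.45 over other cells, by 3.35 with a replicate block and by 1.34 with looser limits, and by 2.23 to 4.11 with 1 library left out.

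Counts of called genes under other tests: DESeq2 called 16 in granulosa cells between regular 10.5-month and young mice and 1 between irregular and regular mice, 58 and 1 in stromal cells, and 330 and 341 in macrophages of acyclic against young and irregular mice. In luteal cells a replicate block gave 960 and resolution 2 gave 1701. In stromal cells of regular 10.5-month against young mice, RLE factors gave 7, no filter 35, a replicate block 13, resolution 2 gave 2 and clusters in both groups 8; of irregular against regular mice, no filter, a replicate block and clusters in both groups gave 1 each. In endothelial cells a replicate block gave 557. In macrophages of acyclic against young mice, no filter gave 340, a replicate block 17, the 2 groups alone 11, doublets kept 58, resolution 2 gave 513 and leaving out acyclic replicates 2 and 3 gave 0; of acyclic against irregular mice the same settings gave 344, 68, 5, 87, 213 and 4, and at most 10% mitochondrial UMIs gave 12. In T cells no filter gave 152, doublets kept 15 and leaving out acyclic replicates 2 and 3 gave 9. With 1 library left out, counts ranged from 2 to 10 in granulosa cells (regular 10.5-month against young), 1164 to 3402 in luteal, 502 to 873 in endothelial and 10 to 57 in T cells, 0 to 251 and 2 to 317 in macrophages (acyclic against young and irregular), and 1694 to 2435, 0 to 8, 0 to 1 and 724 to 1577 in stromal cells (acyclic against young, regular 10.5-month against young, irregular against regular, acyclic against irregular).

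Of 102 lists that passed camera, 0 passed with an estimated correlation and 33 with fry. Direction turned for Hmmr (0.53) in stromal cells of acyclic against young mice and for Cenpe (0.13), Hmmr (0.61) and Prc1 (0.095) against irregular mice with clusters in both groups only, which leaves out cluster 22. The luteal share difference between acyclic and young mice, which did not pass, turned from 2.12 to -0.641 on the log2 scale and to -0.876 without acyclic replicate 4 (-0.876 to 3.78 with 1 library left out). Direction also turned for uncalled genes: Cdkn1a in granulosa cells without acyclic replicates 2 and 3 (-0.14; -0.16 to 0.49 with 1 library left out), Cdkn2b in theca cells with clusters in both groups only (-0.10; -0.076 to 0.31), Cdkn2a in theca cells (-0.21 to 0.69) and Cdkn1a in whole libraries of acyclic against irregular mice (-0.53 to 0.010). It also turned for Cdkn2a in smooth muscle or pericyte, sorted library, with a pseudocount of 5 CPM (-0.063; -0.52 to 0.82 with 1 library left out), for Cdkn2a of sorted stromal cells (-0.16 to 0.32) and for sorted Cdkn1a in smooth muscle or pericyte cells (-0.10 to 1.18). The theca share of sorted cells was 30.2% with at most 10% mitochondrial UMIs, and with their own clustering stromal cells were at 21.2%, granulosa cells at 17.9%, smooth muscle or pericyte cells at 3.79%, T, B, dendritic and mast cells at 0%, and epithelial cells at 3.62%, within the range of acyclic libraries and not below it. Recovery of simulated 2-fold changes was lowest in macrophages, at 55% for acyclic against young, 47% for acyclic against irregular, 28% for regular 10.5-month against young and 23% for irregular against regular mice, and in T cells, at 32%.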

Other observations

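Among the values in this part, the choice of clusters was made after the data were seen, and the tests on splits of the libraries were planned.

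Cdkn2a was high in 1 macrophage cluster and 1 smooth muscle or pericyte cluster. Cluster 36, with 164 macrophages, held 318 counts of Cdkn2a, or 144 CPM (exact 95% interval 129 to 161), and 42.1% of its cells had a UMI of Cdkn2a at a median depth of 10132 UMIs. In granulosa cells 0.261% of cells had one, at a median depth of 23524 UMIs and 0.184 CPM. Of the cells of cluster 36, 114 came from irregular replicate 4, 28 from irregular replicate 1, 12 from young regular replicate 4 and 8 from acyclic replicate 5. Cluster 18 of smooth muscle or pericyte cells was at 33.1 CPM (30.8 to 35.5), with a UMI in 26.0% of cells.

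Unnamed clusters held more of the acyclic libraries. Cluster 15, led by Rhox8, Cdh13, Mro and Tox, held 49.9% and 22.7% of acyclic replicates 2 and 3. Cluster 25, led by Ovgp1, the oviductal glycoprotein, and S100g, held 3.68% ± 2.77 (SD, n = 5) of acyclic and 0.0398% of young cells. Cluster 29, led by Il7r and Trdc, held 1.28% ± 0.727 and 0.223%. Clusters 17 and 24, with few UMIs per cell, held 5.68% ± 1.80 and 2.56% ± 1.65 of acyclic and 1.69% and 0.357% of young cells, and Cmss1, Gphn and Lars2 lead cluster 24. Cluster 37 held 3.55% of acyclic replicate 1, 0.0489% of acyclic replicate 4 and 0% of every other library.

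Other splits of the libraries into groups of the same sizes gave the following numbers of called genes. Between acyclic and young mice, only the real split called as many genes as were found. It was 1 of 60 in granulosa cells (9638, highest other 1357). It was 1 of 100 in luteal (2742 against 0), theca (5119 against 0), stromal (2607 against 51) and macrophage cells (31 against 17). In endothelial (1069 against 1) and T cells (54 against 19) it was 1 of 56. These ranks argue against chance, but were not adjusted over the comparisons, and 126 splits were possible where 60 or 100 were drawn. In macrophages and T cells chance stays open, since the counts depended on single libraries. Between acyclic and irregular mice the ranks argue against chance in granulosa cells (1 of 60, 8958 against 5968) and stromal cells (1 of 35, 1572 against 8). They do not in macrophages, where 6 of 100 splits called at least the real 22 and the highest called 391. Between peri-estropausal regular and young mice the count alone argues against chance in granulosa cells (1 of 56, 3 against 1). These are 3 genes near the floor, Gm15127, Gm10439 and Luzp4, with group means of 0.0294 to 4.62 CPM, so little rests on that count. In stromal cells and macrophages of that comparison, and between irregular and regular mice in granulosa, stromal and macrophage cells, the real count was 0, which all 56 and all 35 splits reach by construction, so there were no calls for chance to explain (highest other 2 and 0, and 8, 272 and 303). Some splits thus called 272 and 303 genes where the real one called 0, and 391 where it called 22. The splits with 303 and 391 macrophage calls both put irregular replicates 1 and 4 on the same side. Those libraries held 28 and 114 cells of macrophage cluster 36. Whether that cluster, single libraries or another structure of the samples made these calls was not tested. For irregular against regular mice, 8 splits part all 3 same-number pairs, the real one included. Among these the highest other count was 0 in granulosa, 0 in stromal and 303 in macrophage cells, and among the rest it was 8, 272 and 90.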
